A study of Mus musculus with 36 samples.

How the data were processed

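Macrophages from collagenase-treated aortas, monocytes from blood and spleen after red cell lysis, and macrophages from peritoneal lavage of Apoe-deficient mice were sorted by flow cytometry straight into lysis buffer, per the labels' protocols. RNA was purified on small-input columns and made into libraries with the Ovation SoLo kit, which is meant for very low RNA input, and sequenced in paired ends on a NextSeq500, per the labels' protocols. The labels give the molecule as polyA RNA. The deposited values are whole-number counts of reads per gene, 1 file per library. The submitters' processing notes name the aligner STAR, the counter featureCounts and the assembly mm10, and versions and settings were not given. Whether counting used strand is not stated, so antisense and overlapping genes, and genes with near-identical copies such as Lyz1 and Lyz2 and the ribosomal protein genes, are uncertain.

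Each file holds 24421 genes, of which 18168 had a count in some library. Every gene has a name, and 23204 of the symbols match RefSeq's annotation of GRCm38.p6, or 24312 with synonyms. No files were identical. Totals ran from 0.943 to 14.8 M reads. Rn45s took 4.74 to 19.8% of the reads and was kept in the totals. The counts carry no molecular identifiers, so counting intervals and the floor of 3 counts cover counting error only. The biological coefficient of variation, which sets the precision of a fold change beside the depth, was 110% in the aorta, 19.1% in monocytes, 21.2% in the peritoneum and 65% over all 36 libraries.

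Groups were taken from the sample titles. Stages were compared within each population in a fit of its 12 libraries with stage as the only factor. Populations, averaged over stages, and differences in response were compared in one fit of all 36 libraries with 9 groups. The test was edgeR's (4.0.16, R 4.3.3) quasi-likelihood test on the deposited counts with TMM normalisation, genes kept by filterByExpr, and a Benjamini-Hochberg adjusted p under 0.05, two-sided. The standard error is the absolute log2 fold change over the square root of F. Gene lists of pathways, cell states and other cell types were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Its p, for a list against all other genes, was adjusted over the lists of a comparison. The same test was run with the correlation between genes estimated from the data. Lists for adipocytes, mesothelium and mitochondrially encoded transcripts had too few measured genes for a test. Shared responses were set against unchanged groups simulated on the same baseline libraries (20 simulations), against the number expected of independent lists, and with the baseline libraries divided.

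Named genes were chosen by a rule. For early against baseline and advanced against early it took the 8 higher and 8 lower genes with the largest change among those that passed, had no overlap between the libraries of the 2 groups and reached a mean of 20 CPM in the higher group, without predicted symbols. For advanced against baseline, populations and responses it took 5 and 5, for responses without the overlap condition and for populations with the same sign at all 3 stages in its place. Up to 4 passing members with the smallest p were added from each list, with Apoe and the sex-linked genes as checks of the labels. Genes were dropped from the end of the ranking to keep the text short, and genes named from the fit with a separate spread were chosen after their values were seen. Some genes that the rule names are not reported here.

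The alternatives were RLE size factors, no filter, DESeq2 (1.42.0), limma-voom with quality weights, a replicate block, counts thinned to the shallowest library, a fit of all 36 libraries, and each library left out in turn. Added after seeing the data were fits without the libraries that stood apart, without Rn45s, with one weight per population and with a separate spread per population. Other splits of the libraries were counted, all 35 of 4 against 4 and 60 drawn elsewhere. Each step was tested on simulated counts with 200 genes changed. edgeR recovered 27.7, 66.7 and 93.8% of genes changed 1.5-, 2- and 4-fold for early against baseline in monocytes (9260 genes, 5 of 127 calls false), 18.5, 65.7 and 100% in the peritoneum (9445 genes, 5 of 126 false), and 0, 0 and 13.6% in the aorta (9106 genes, 1 of 9 false), where 30 of 45 DESeq2 calls were false. In simulated counts with each population's own spread, most calls of the fit of all 36 libraries were false for the responses (66 of 83, 77 of 95, 60 of 81 and 53 of 76 among 10771 genes) and for the aorta against monocytes or the peritoneum (428 of 518 and 441 of 532 among 10617 genes). A ribosomal protein list raised 1.5-fold was recovered by camera in each population, while 2 of the other lists were called in monocytes and none elsewhere, and 1 list in an unchanged monocyte comparison.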

Results

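RNA was sequenced from 3 sorted cell populations of Apoe-deficient mice, which lack apolipoprotein E, clear cholesterol-rich lipoproteins poorly and develop atherosclerosis. The populations were macrophages from enzymatically digested aortas, monocytes from blood and spleen, and macrophages washed from the peritoneal cavity. Each was taken at baseline (chow diet), at an early stage (1 month of high cholesterol diet) and at an advanced stage (6 months), with 4 libraries in each of the 9 groups and 36 in all. The series asks how gene regulation changes in systemic and lesional monocytes and macrophages as atheroma starts and progresses. The labels do not say whether the 4 libraries of a group came from separate mice, so p-values measure the spread between these samples only. Values after a gene name are log2 fold changes ± standard error with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test on 4 libraries per group, unless another unit is named. All comparisons, gene lists and the rule for naming genes were fixed before the data were examined.

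Depth differed between the stages. The 12 baseline libraries held 5.28 to 14.8 M counted reads and the other 24 held 0.943 to 2.63 M. In aortic macrophages the group means were 8.17 ± 2.02, 1.98 ± 0.538 and 2.02 ± 0.648 M at baseline, early and advanced stage (SD, n = 4). They were, in monocytes, 11.6 ± 2.46, 1.99 ± 0.289 and 1.38 ± 0.317 M, and in peritoneal macrophages 11.4 ± 2.21, 1.95 ± 0.514 and 1.89 ± 0.231 M. In each population every baseline library was deeper than every early one (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). Baseline therefore cannot be told apart from a deeper sequencing run. Between the advanced and early stages the exact permutation p for depth was 0.914 in aortic macrophages, 0.0571 in monocytes, whose advanced libraries were shallower on average, and 0.83 in peritoneal macrophages. Thinned to the total of the shallowest library, aortic libraries held 8244 ± 1464 detected genes at baseline, 9736 ± 507 early and 11366 ± 1491 at the advanced stage (SD, n = 4). Monocyte and peritoneal groups held 11389 to 11615 genes on average. The share of reads from the ribosomal RNA precursor Rn45s also moved with stage, from 8.96 to 13.1% between baseline and early stage in monocytes and from 5.41 to 10.04% between baseline and advanced stage in the aorta (both exact permutation p = 0.0286).

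**Figure D1:**
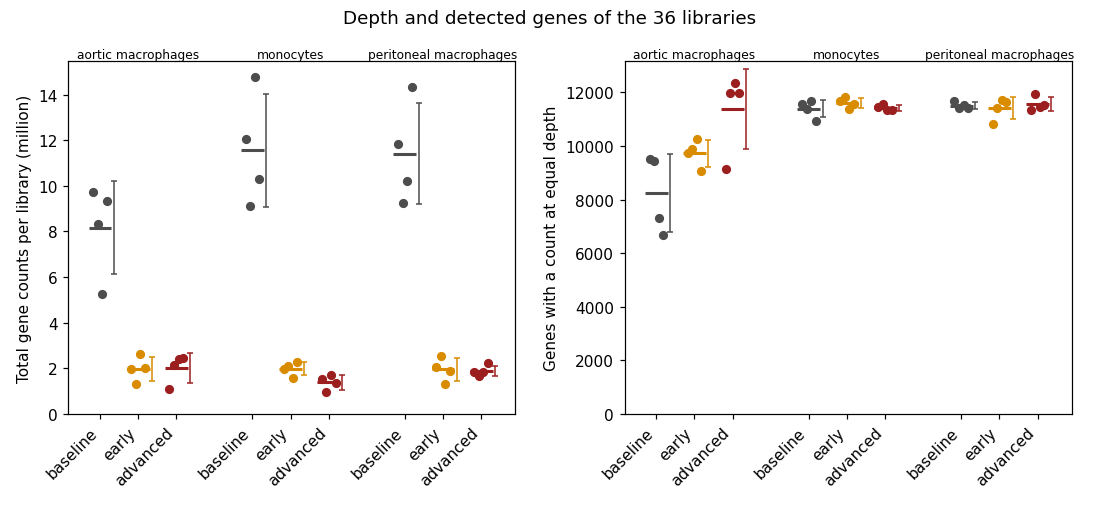
Total gene counts per library in M (left) and genes with a count after thinning to equal depth (right) for the 9 groups of population and stage; dots are libraries, horizontal lines group means and side bars SD (n = 4). Every baseline library (5.28 M or more) lies above every early or advanced library (2.63 M or fewer).

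Replicates resembled each other closely in monocytes and less so in the aorta. Spearman correlations between libraries of a group, over genes, were 0.949 to 0.987 in monocytes, 0.854 to 0.971 in early peritoneal macrophages and at least 0.959 in the other peritoneal groups. In aortic macrophages they were 0.47 to 0.732 at baseline, 0.708 to 0.793 early and 0.784 to 0.957 at the advanced stage. The biological coefficient of variation was 110% in the aorta, 19.1% in monocytes and 21.2% in the peritoneum. All 36 libraries correlated best with their own population. Aortic baseline libraries 3 and 4, aortic advanced library 1, monocyte advanced library 3 and peritoneal early libraries 1 and 2 stood apart from their groups. Each count was repeated without them, a choice made after seeing the data.

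Apoe, the disrupted gene, lies on chromosome 7 (19696244 to 19701310; all coordinates are whole genes in RefSeq's annotation of GRCm38.p6, the assembly also called mm10). Its reads were counted in every library. In aortic macrophages it reached 32.6, 2.96, 2.48 and 40.2 CPM (counts scaled to the library's total) in the 4 baseline libraries, 70.0, 99.1, 31.1 and 39.7 in the early ones and 109.7, 27.6, 40.6 and 42.8 in the advanced ones. Monocytes had 11.3, 6.70, 11.4 and 6.65, then 39.9, 11.1, 12.6 and 7.83, then 2.52, 8.57, 10.1 and 10.5 CPM. Peritoneal macrophages had 6.75, 5.88, 8.12 and 7.67, then 110.4, 19.5, 8.65 and 10.8, then 6.02, 5.86, 4.85 and 3.77 CPM. The labels do not say which part of Apoe is deleted, so counts over the whole gene do not check the genotype. Apoe passed the test in none of the 9 stage comparisons (edgeR; the nearest was 2.47 ± 0.60, adjusted p = 0.0501, early against baseline in the peritoneum). Xist, transcribed from the inactive X chromosome, reached 1124 to 8500 CPM in all 36 libraries, while the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 7, 3, 1 and 0 counts over all of them.

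The populations differed, averaged over the 3 stages. Aortic macrophages exceeded monocytes in every measured member of the list for resident arterial macrophages that carry the hyaluronan receptor LYVE1, such as Lyve1 (12.20 ± 0.34; chromosome 7, 110850607 to 110862953), and in the complement genes C1qa (7.71 ± 0.27), C1qb (7.05 ± 0.19) and C1qc (7.54 ± 0.27). They also exceeded both other populations in the inflammatory chemokine Ccl2 (6.29 ± 0.42 against monocytes and 6.44 ± 0.43 against peritoneal macrophages) and in Tnf (4.34 ± 0.34 and 7.02 ± 0.41). Retnla, a secreted protein of alternatively activated macrophages, had no count in monocytes and was at least 30000-fold higher in aortic and at least 8060-fold higher in peritoneal macrophages, against a floor of 3 counts over the 12 monocyte libraries. Monocytes were higher in Ly6c2 (-11.66 ± 0.57 for aorta against monocytes), a surface marker of classical monocytes, and in Hp (-8.20 ± 0.44), which encodes haptoglobin. Peritoneal macrophages were higher in Prg4 (14.24 ± 0.66 against monocytes), the lubricating proteoglycan of serosal surfaces, and in Icam2 (-9.71 ± 0.38 for aorta against peritoneum), an adhesion molecule.

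The fixed lists also separated the populations. All 16 LYVE1 list members were higher in aortic macrophages than in monocytes (16 adjusted over the list alone; camera adjusted p = 1.84e-35, and 2.36e-06 with an estimated correlation). So were all 19 immediate-early and heat-shock genes (19 adjusted over the list alone; 1.96e-19 and 0.00519) and 16 of 17 NF-kB inflammatory genes (17 adjusted over the list alone; 1.86e-16 and 0.0103). All 16 genes of the large peritoneal macrophage list, which centres on the transcription factor GATA6, were higher in the peritoneum than in monocytes (16 adjusted over the list alone; 1.19e-26 and 1.23e-05). All were lower in the aorta than in the peritoneum (16 adjusted over the list alone; 1.68e-18 and 2.84e-04). Monocytes were higher than peritoneal macrophages in all 11 nonclassical monocyte genes, such as Cx3cr1 (-8.12 ± 0.40; 11 adjusted over the list alone; 1.31e-12 and 0.00108). They were also higher in 15 of 22 interferon response genes (17 adjusted over the list alone; 1.94e-07 and 0.0254). Of 22 SREBP2 genes of cholesterol synthesis and uptake, 11 were higher in peritoneal macrophages than in monocytes (11 adjusted over the list alone; camera adjusted p = 0.00258, against adjusted p = 0.104 with an estimated correlation). Of 29 ribosomal protein genes, 25 were lower in the aorta than in the peritoneum (25 adjusted over the list alone; camera adjusted p = 2.62e-05, against adjusted p = 0.127 with an estimated correlation).

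Markers of other cells also separated the sorts. All 7 fibroblast markers were higher in the aortic libraries than in monocytes (7 adjusted over the list alone; 7.06e-10, and adjusted p = 0.00318 with an estimated correlation), with Dcn at 8.82 ± 0.82 and Col1a2 at 9.48 ± 0.77. All 8 neutrophil markers were lower there than in monocytes (8 adjusted over the list alone; 1.61e-10, and adjusted p = 0.00519 with an estimated correlation). S100a9 had 1 count in the 12 aortic libraries together, and its ratio of monocytes to aorta was 56700 with a counting interval of 10200 to 2240000. In all, 4044 of 11052 genes differed between aortic macrophages and monocytes (2031 higher, 2013 lower), 3769 between aortic and peritoneal macrophages (1888 and 1881) and 3293 between peritoneal macrophages and monocytes (1659 and 1634). The noisier aorta inflated calls in this fit of all 36 libraries. In simulated counts with these spreads, 428 of 518 calls for aorta against monocytes and 441 of 532 for aorta against peritoneum were false. Peritoneum against monocytes gave none (edgeR). False shares depend on how many genes differ, so these do not carry over to real calls. With one weight per population, chosen after seeing the data, the 3 numbers were 2877 (1058 higher, 1819 lower), 2689 (923 and 1766) and 6892 (3470 and 3422). In simulated counts 352 of 413 and 354 of 421 aortic calls of that fit were false too, and unchanged genes had medians of -0.43 (0.15 in edgeR), so neither fit settles the balance of higher and lower genes.

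In aortic macrophages the early stage was compared with baseline to see what changed as lesions began. Genes that rose included Cxcl2 (2.56 ± 0.31, adjusted p = 2.70e-04), which attracts neutrophils, Ccl3 (3.17 ± 0.48, adjusted p = 0.00318), which attracts monocytes, and the transcription factors Fos (2.11 ± 0.22, adjusted p = 3.42e-05) and Atf3 (2.64 ± 0.40, adjusted p = 0.00318). Il10, an anti-inflammatory cytokine, rose from 0.336 to 52.0 ± 40.6 CPM (SD, n = 4; adjusted p = 0.00935). Clec4e encodes Mincle, a receptor for dead cells and mycobacterial glycolipid (chromosome 6, 123281789 to 123289871). It had no count in the 4 baseline libraries and 118.1 ± 52.8 CPM early (adjusted p = 2.17e-06). Against a floor of 3 counts over the group that is at least 1280-fold, for counting error only, as lost transcripts also read 0. Lyz1, a lysozyme gene, fell from 751 ± 135 to 148 ± 52.4 CPM (-2.36 ± 0.41, adjusted p = 0.0126), and Fn1, fibronectin (chromosome 1, 71585473 to 71653280), fell from 3846 ± 883 to 861 ± 158 CPM (-2.17 ± 0.28, adjusted p = 3.69e-04). Lpl, lipoprotein lipase, fell as well (-1.73 ± 0.32, adjusted p = 0.0166).

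Of 17 NF-kB inflammatory genes, 3 rose and none fell, and 13 rose adjusted over the list alone (camera adjusted p = 1.87e-08, against adjusted p = 0.193 with an estimated correlation). Immediate-early and heat-shock genes rose in 7 of 19 (13 adjusted over the list alone; camera adjusted p = 2.31e-08, against adjusted p = 0.193 with an estimated correlation), including Zfp36 (1.67 ± 0.32) and Jun (1.70 ± 0.33). MHC class II genes, which present antigen, had negative fold changes in all 9 members, none of which passed over all genes, while 6 fell adjusted over the list alone. The list fell (camera adjusted p = 1.02e-04, against adjusted p = 0.193 with an estimated correlation). Lists for SREBP2 targets and small peritoneal macrophages fell (camera adjusted p = 0.0225 and 0.0496, against adjusted p = 0.193 and 0.193 with an estimated correlation). Those for TREM2 lipid-associated macrophages and nonclassical monocytes rose (0.0476 and 0.0457, against adjusted p = 0.37 and 0.419 with an estimated correlation). In the TREM2 list Gpnmb, a lysosomal glycoprotein of foam cells (chromosome 6, 49036518 to 49058182), rose and Lpl fell. Gpnmb had no count at baseline and was at least 74-fold higher early against the same floor. Fibroblast markers moved with these groups: their mean log2(CPM + 1) was 0.784 to 3.80 in baseline libraries and 4.79 to 6.42 in early ones. The list rose (camera adjusted p = 1.58e-05, against adjusted p = 0.193 with an estimated correlation), with 1 of 7 called and 6 adjusted over the list alone.

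In all, 37 of 9920 genes changed (31 higher, 6 lower), where the spread in the aorta recovered 13.6% of genes changed 4-fold and none of those changed 2-fold in simulated counts. Without the libraries that stood apart 114 genes passed (98 higher, 16 lower), DESeq2 called 704, and edgeR without a filter on low counts called 151. Leaving out single libraries gave 18 without baseline 1, 120 without baseline 4, 12 without early 1, 21 without early 2 and 23 without early 3 or early 4. Of the 20 named genes 9 kept their call in all 8 such fits. The call was lost for Lpl without baseline 1 or early 3 or 4 (adjusted p up to 0.0653), Zfp36 without baseline 1 or 2 or early 1 or 2 (adjusted p up to 0.1) and Jun without baseline 1, 2 or 3 or early 1, 2 or 4 (adjusted p up to 0.125).

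The advanced stage was compared with the early stage in aortic macrophages to follow progression. Ctsd, the lysosomal protease cathepsin D (chromosome 7, 142375910 to 142387827), rose from 455 ± 15.7 to 1470 ± 262 CPM (1.68 ± 0.23, adjusted p = 0.00559). Fn1 rose from 861 ± 158 to 2546 ± 1150 CPM (1.56 ± 0.27, adjusted p = 0.0302), and Nr4a3, an inducible nuclear receptor, from 42.1 to 345 ± 112 CPM (3.02 ± 0.48, adjusted p = 0.0166). Filip1l, a regulator of cell migration, fell (-1.92 ± 0.33, adjusted p = 0.0302).

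The TREM2 lipid-associated list rose, with 1 of 16 members called (5 adjusted over the list alone; camera adjusted p = 4.70e-07, against adjusted p = 0.0638 with an estimated correlation). The lysosome list rose too, with 1 of 25 called (6 adjusted over the list alone; 1.34e-05, against adjusted p = 0.0638 with an estimated correlation). Ctsd belongs to both. Genes of resident LYVE1 macrophages fell as a list with no member called over all genes (1 higher and 6 lower adjusted over the list alone; 8.75e-05, against adjusted p = 0.174 with an estimated correlation). Nonclassical monocyte genes fell as well (1.36e-04, against adjusted p = 0.119 with an estimated correlation). Lists for matrix proteases, glycolysis and hypoxia, MHC class II, NRF2 antioxidant genes, LXR targets and the cell cycle rose with no member called over all genes (camera adjusted p = 3.15e-04, 0.00111, 0.00509, 0.00874, 0.0246 and 0.0287). For these the adjusted p = 0.101, 0.106, 0.221, 0.119, 0.106 and 0.499 with an estimated correlation, and 2, 0, 3, 1, 0 and 0 members rose adjusted over the list alone. The GATA6 list rose too (6.24e-05, against adjusted p = 0.106 with an estimated correlation), with Fn1 its called member. Fibroblast markers, at 2.97 to 4.67 mean log2(CPM + 1) in advanced libraries, fell as a list (6.24e-05, against adjusted p = 0.106 with an estimated correlation).

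These 4 genes were the ones called among 9920, with 354 at an unadjusted p under 0.05. The call was kept for all 4 among the 34 that passed without the libraries that stood apart (27 higher, 7 lower), 47 by DESeq2, 40 without the filter and 235 by limma-voom with quality weights (150 higher, 85 lower). At equal depth 7 passed (6 higher, 1 lower). Leaving out early 1, 2 or 4 left 1 gene, leaving out advanced 1, 2 or 4 left 2, and leaving out early 3 or advanced 3 left 0. The call was lost for Ctsd without early 3 or advanced 3 (adjusted p up to 0.0653), Fn1 without early 1, 2, 3 or 4 or advanced 1 or 3 (adjusted p up to 0.193), Nr4a3 without early 1, 2, 3 or 4 or advanced 2, 3 or 4 (adjusted p up to 0.109) and in all 8 fits for Filip1l.

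From baseline to the advanced stage, several genes known from foam cells or inflammation rose in aortic macrophages. Gpnmb went from no count to 274 ± 138 CPM (SD, n = 4; at least 3510-fold higher against the floor of 3 counts; adjusted p = 8.41e-05), and Clec4e from none to 166.2 ± 43.4 CPM (at least 2050-fold higher; adjusted p = 1.38e-06). Ctsd (2.06 ± 0.24, adjusted p = 8.41e-05), the cathepsin Ctsb (1.19 ± 0.20, adjusted p = 0.00432) and Plin2, which coats lipid droplets (1.88 ± 0.31, adjusted p = 0.00432), rose, as did Cxcl2 (3.28 ± 0.32, adjusted p = 1.14e-05) and Cxcl1 (4.19 ± 0.68, adjusted p = 0.00404). Lyz1 (-2.23 ± 0.41, adjusted p = 0.0102) and the scavenger receptor Stab1 (-1.01 ± 0.21, adjusted p = 0.0275) fell.

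Of 16 TREM2 list members 5 rose and none fell (9 adjusted over the list alone; camera adjusted p = 1.22e-08, against adjusted p = 0.0777 with an estimated correlation). NF-kB genes rose in 6 of 17 (16 adjusted over the list alone; 5.73e-12, against adjusted p = 0.155 with an estimated correlation). Immediate-early and heat-shock genes rose in 7 of 19 (8 adjusted over the list alone; 2.13e-05, against adjusted p = 0.331 with an estimated correlation). NRF2 antioxidant genes rose as a list with 1 of 13 called, Hmox1, the heme-degrading oxygenase (1.54 ± 0.31; 8 adjusted over the list alone; 2.11e-04, against adjusted p = 0.105 with an estimated correlation). Lysosomal genes rose in 4 of 25 (7 adjusted over the list alone; 0.0369, against adjusted p = 0.324 with an estimated correlation). Matrix proteases and the GATA6 list rose (both 0.0134, against adjusted p = 0.2 and 0.331 with an estimated correlation). Lists for dendritic cells, small peritoneal macrophages and LYVE1 macrophages fell (0.00463, 0.0124 and 0.0399, against adjusted p = 0.109, 0.124 and 0.385 with an estimated correlation), although Ccl8, a LYVE1 list member, rose (2.95 ± 0.60). The scavenger receptor list had a median and a test of opposite sign and did not pass.

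In all 58 genes passed (53 higher, 5 lower), and 173 without the libraries that stood apart (163 higher, 10 lower), 93 at equal depth (88 higher, 5 lower), 548 by DESeq2, 165 without the filter and 151 by limma-voom with quality weights. The count was 35 without baseline 1, 33 without baseline 2, 154 without baseline 4, 33 without advanced 3 and 32 without advanced 4. Of the 26 named genes 13 kept their call in all 8 fits. Calls were lost for Stab1 without baseline 1 or 2 or advanced 2, 3 or 4 (adjusted p up to 0.14), Hmox1 without baseline 1 or 2 or advanced 3 or 4 (adjusted p up to 0.124) and Ccl8 without baseline 1 or 2 or advanced 1 or 3 (adjusted p up to 0.0741).

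**Figure D2:**
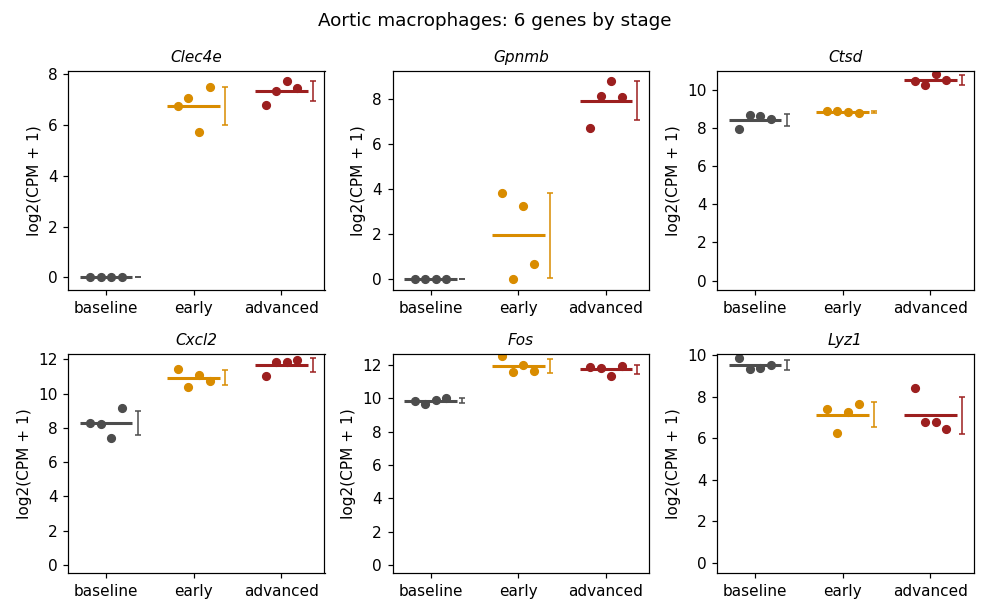
log2(CPM + 1) of 6 genes in the aortic macrophage libraries by stage; dots are libraries, horizontal lines group means and side bars SD (n = 4). Clec4e and Gpnmb lie at 0 in all 4 baseline libraries, and Lyz1 lies lower in early and advanced libraries than at baseline.

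In monocytes the early stage was compared with baseline to follow the cells that supply lesions. Genes that rose included the ribosomal protein genes Rps16 at 0.74 ± 0.08 and Rplp1 at 1.21 ± 0.14 and the DNA replication helicase subunit Mcm6 at 1.45 ± 0.29. Abca1, the cholesterol efflux transporter, rose from 165 to 343 CPM (1.06 ± 0.18, adjusted p = 0.00222). The fractalkine receptor Cx3cr1 fell (-0.68 ± 0.17, adjusted p = 0.017). The largest rises belonged to markers of other blood cells: S100a8 (chromosome 3, 90669071 to 90670034; 5.18 ± 0.73, adjusted p = 7.21e-04) and S100a9 (chromosome 3, 90692630 to 90695721; 4.92 ± 0.76, adjusted p = 0.00113), which are most abundant in neutrophils, and the granzyme Gzma of cytotoxic lymphocytes (chromosome 13, 113093824 to 113100981; 5.66 ± 1.03, adjusted p = 0.00343).

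Of 29 ribosomal protein genes 23 rose (25 adjusted over the list alone; median log2 fold change 0.45; camera adjusted p = 3.95e-20, against adjusted p = 0.17 with an estimated correlation). Of 25 nuclear-encoded oxidative phosphorylation genes 7 rose (8 adjusted over the list alone; 8.89e-06, against adjusted p = 0.225 with an estimated correlation). The median of the latter, 0.24, lay inside the 95% range of genes matched on transcript length and expression (-0.01 to 0.28). Cell cycle genes rose in 7 of 25 (15 adjusted over the list alone; 2.71e-09, against adjusted p = 0.32 with an estimated correlation). Immediate-early and heat-shock genes rose in 5 of 17 (7 adjusted over the list alone; 3.46e-04, against adjusted p = 0.508 with an estimated correlation). Lists for LXR targets, TREM2 macrophages, NF-kB, interferon and MHC class II genes rose (0.0269, 0.0295, 0.0457, 0.0457 and 0.0352, against adjusted p = 0.32, 0.32, 0.602, 0.733 and 0.602 with an estimated correlation), with 1, 3, 2, 2 and 1 members called. SREBP2, lysosomal and nonclassical lists fell (0.0334, 0.0404 and 0.0222, against adjusted p = 0.225, 0.602 and 0.586 with an estimated correlation), with 1, 3 and 3 members called lower and 1 lysosomal gene, Ctsl, higher (1.06 ± 0.30).

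Other-cell markers moved with these groups. Neutrophil markers rose in 6 of 8 and Csf3r fell (-0.60 ± 0.11; 6 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.61e-04, against adjusted p = 0.32 with an estimated correlation). Their mean log2(CPM + 1) went from 3.36 to 5.97 in baseline libraries to 6.96 to 8.86 early and 8.0 to 10.2 at the advanced stage. T and NK cell markers rose in 8 of 10 and B cell markers in 4 of 5 (10 and 5 adjusted over the list alone; 7.83e-06 and 9.46e-04, against adjusted p = 0.32 and 0.32 with an estimated correlation). Their early means were 2.99 to 6.14 and 2.59 to 4.46, against 1.56 to 2.87 and 1.53 to 3.11 at baseline. All 3 erythroid markers fell (3 adjusted over the list alone; 1.09e-04, against adjusted p = 0.17 with an estimated correlation), such as the band 3 gene Slc4a1 (chromosome 11, 102348820 to 102365281; -5.25 ± 0.90).

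In all 1023 of 9465 genes changed (543 higher, 480 lower) and 312 of them at least 2-fold. At equal depth 574 passed (319 higher, 255 lower). Without monocyte advanced 3 the count was 1100, and in the fit of all 36 libraries, whose spread the aorta widened, it was 17. Leaving out baseline 1 gave 637, baseline 2 621, early 1 621, early 2 548 and early 4 656. Of the 66 named genes 44 kept their call in all 8 fits. Calls were lost for Cx3cr1 without early 2 (adjusted p up to 0.0642) and Ctsl without baseline 1, 2 or 4 or early 1 or 2 (adjusted p up to 0.159).

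Between the early and advanced stages in monocytes, Adam8, a surface protease of activated leukocytes (1.70 ± 0.25, adjusted p = 0.00696), and F5, coagulation factor V (1.23 ± 0.18, adjusted p = 0.00696), rose. Lef1 (-4.57 ± 0.63, adjusted p = 0.00696), a T cell transcription factor, Cd3g (-4.26 ± 0.68, adjusted p = 0.00838) and Cd79b (-1.94 ± 0.34, adjusted p = 0.0127) of the T and B cell receptor complexes fell, and so did the lymph node homing receptor Ccr7 (-3.76 ± 0.60, adjusted p = 0.00838). Ear1, an eosinophil ribonuclease with 3 counts over the early group, had an advanced to early ratio of 95.9 (counting interval 32.3 to 469), and Retnlg, a neutrophil transcript, rose (4.29 ± 0.84, adjusted p = 0.019).

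All measured T and NK cell markers had negative fold changes and 7 of 10 fell (10 adjusted over the list alone; camera adjusted p = 6.44e-11, against adjusted p = 0.122 with an estimated correlation), with advanced libraries at 1.39 to 2.18 mean log2(CPM + 1). B cell markers fell in 2 of 5 (5 adjusted over the list alone; 5.64e-05, against adjusted p = 0.122 with an estimated correlation). Dendritic cell markers fell in 1 of 6 (6 adjusted over the list alone; 5.23e-06). Matrix proteases rose in 2 of 9 (4 adjusted over the list alone; 3.80e-04), and these were the list calls here that held with an estimated correlation (adjusted p = 0.0182 and 0.0368). Ribosomal protein genes fell in 5 of 29 (15 adjusted over the list alone; median -0.24; 4.65e-08, against adjusted p = 0.227 with an estimated correlation), such as Rpl13 (-0.57 ± 0.09). MHC class II, interferon and immediate-early lists fell (5.97e-04, 0.0177 and 0.0211, against adjusted p = 0.438, 0.779 and 0.779 with an estimated correlation). Unfolded protein response, GATA6 and erythroid lists rose (0.0127, 0.0211 and 0.0366, against adjusted p = 0.121, 0.122 and 0.378 with an estimated correlation).

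In all 194 genes changed (64 higher, 130 lower). Without monocyte advanced 3 the count was 91 (43 higher, 48 lower), DESeq2 called 502, limma-voom with quality weights 133 with a different balance (66 higher, 67 lower). edgeR without a filter called 373, and the fit of all 36 libraries called 0 (299 at an unadjusted p under 0.05 in edgeR). Leaving out early 2 gave 34, early 3 321, early 4 128, advanced 1 52, advanced 2 69, advanced 3 91 and advanced 4 103. Of the 34 named genes 10 kept their call in all 8 fits. Calls were lost for Ear1 without early 1, 2 or 4 or advanced 1 or 2 (adjusted p up to 0.0928) and Retnlg without early 2 or advanced 2 (adjusted p up to 0.0722).

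From baseline to the advanced stage in monocytes, Tyms, thymidylate synthase (3.44 ± 0.58, adjusted p = 0.00111), and Top2a, a mitotic topoisomerase (2.63 ± 0.52, adjusted p = 0.00329), rose. S100a8 went from 70.9 ± 51.6 to 4565 ± 4570 CPM (5.97 ± 0.76, adjusted p = 2.49e-04) and S100a9 from 106 ± 84.3 to 6220 ± 6250 CPM (SD, n = 4; 5.84 ± 0.79, adjusted p = 3.35e-04). Advanced library 3 held 11260 and 15370 CPM, and the other 3 held 1340 to 3681 and 1892 to 5090. Abca1 (0.97 ± 0.18, adjusted p = 0.0023), the lipid droplet gene Plin2 (1.12 ± 0.18, adjusted p = 9.09e-04) and Cd63, a tetraspanin of lysosomes (3.44 ± 0.49, adjusted p = 4.45e-04), rose, while Cx3cr1 (-0.89 ± 0.17, adjusted p = 0.00241) and the dendritic cell cytokine receptor Flt3 (-1.06 ± 0.20, adjusted p = 0.00271) fell.

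Cell cycle genes rose in 16 of 25 (24 adjusted over the list alone; camera adjusted p = 2.73e-09, against adjusted p = 0.411 with an estimated correlation). Oxidative phosphorylation genes rose in 8 of 25 (9 adjusted over the list alone; 2.25e-04, against adjusted p = 0.343 with an estimated correlation). Ribosomal protein genes rose in 11 of 29 (12 higher and 1 lower adjusted over the list alone; 6.13e-05, against adjusted p = 0.411 with an estimated correlation). The TREM2 list rose with 4 of 13 called and the unfolded protein response list with 4 of 12, such as the chaperone Hspa5 at 0.44 ± 0.09 (5 and 5 higher adjusted over the list alone; 0.0363 and 0.0156, against adjusted p = 0.411 and 0.186 with an estimated correlation). Nonclassical genes fell in 5 of 11 (5 adjusted over the list alone; 0.0224, against adjusted p = 0.646 with an estimated correlation). Dendritic cell markers fell in 5 of 6 (6 adjusted over the list alone; 2.25e-04, against adjusted p = 0.0634 with an estimated correlation). Neutrophil markers rose in 7 of 8 (8.33e-05, against adjusted p = 0.343 with an estimated correlation). All 3 erythroid markers fell (0.0272, against adjusted p = 0.392 with an estimated correlation). Both moved with the groups above.

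In all 1798 genes changed (875 higher, 923 lower). The count was 1182 without monocyte advanced 3, whether left out alone or as the library that stood apart (559 higher, 623 lower), 1070 at equal depth (523 higher, 547 lower) and 33 in the fit of all 36 libraries. Of the 71 named genes 47 kept their call in all 8 fits, including all those given above with a value from this comparison.

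**Figure D3:**
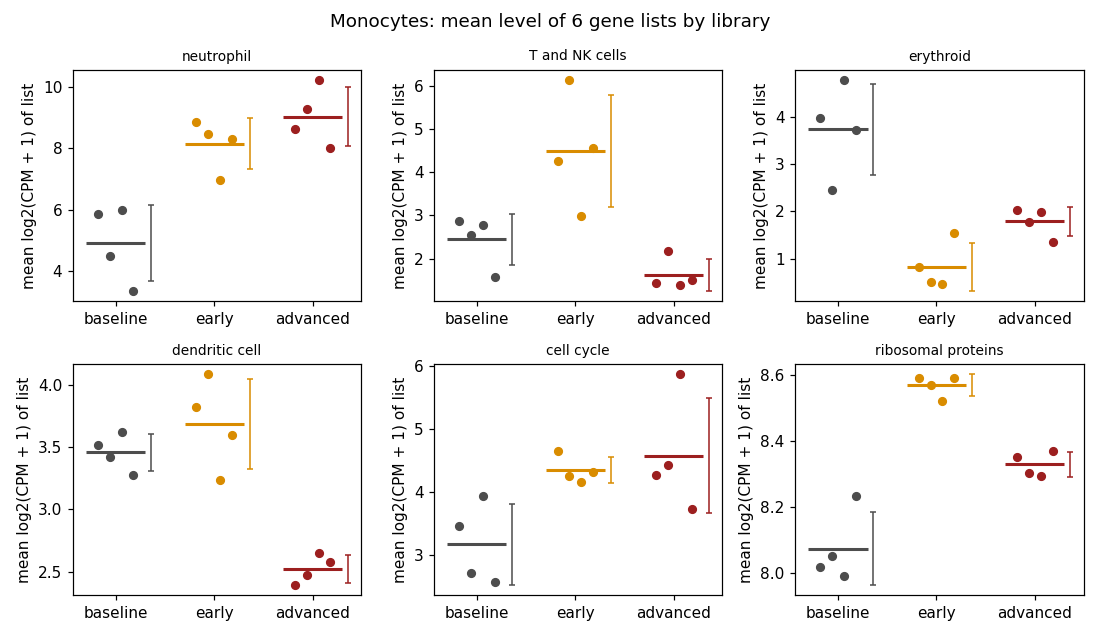
Mean log2(CPM + 1) of 6 gene lists in the monocyte libraries by stage, with a separate vertical scale in each panel; dots are libraries, horizontal lines group means and side bars SD (n = 4). Neutrophil markers lie at 3.36 to 5.97 at baseline and 8.0 to 10.2 at the advanced stage, and T and NK cell markers are highest in early libraries (2.99 to 6.14).

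In peritoneal macrophages, which sit away from the lesion, the early stage was compared with baseline to follow a systemic response. Marco, a scavenger receptor for bacteria and particles (chromosome 1, 120474538 to 120505024), fell from 254 ± 79.4 to 36 ± 10.8 CPM (SD, n = 4; -2.76 ± 0.32, adjusted p = 0.00395), and Arg1, arginase of alternatively activated macrophages (-1.75 ± 0.27, adjusted p = 0.0099), and Lyve1 (-1.62 ± 0.32, adjusted p = 0.0279) fell. Jun rose from 107 to 619 ± 243 CPM (2.58 ± 0.37, adjusted p = 0.0099) and Egr1, another immediate-early factor, rose (3.71 ± 0.58, adjusted p = 0.0105), as did the monocyte chemokine Ccl2 (4.19 ± 0.64, adjusted p = 0.0099). Ccr2, the receptor for Ccl2 (chromosome 9, 124101918 to 124109140), went from 11.9 ± 2.69 to 576 ± 638 CPM (5.66 ± 0.94, adjusted p = 0.0132), Fcrls (chromosome 3, 87250736 to 87263765) from 1.51 to 107 ± 158 CPM (6.24 ± 0.95, adjusted p = 0.0099) and the MHC class II gene H2-Ab1 from 32.9 to 619 ± 799 CPM (4.31 ± 0.97, adjusted p = 0.0406). The SDs of these 3 exceeded their early means because early libraries 1 and 2 stood apart.

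Immediate-early and heat-shock genes rose in 10 of 17 (16 adjusted over the list alone; camera adjusted p = 1.23e-12, against adjusted p = 0.278 with an estimated correlation). Ribosomal protein genes rose in 5 of 29 (23 adjusted over the list alone; median 0.51; 3.26e-15, against adjusted p = 0.291 with an estimated correlation). Oxidative phosphorylation genes rose in 1 of 25 (8 adjusted over the list alone; 5.45e-05, against adjusted p = 0.291 with an estimated correlation), and their median of 0.35 lay inside the range of genes matched on length and expression (0.07 to 0.38). MHC class II genes rose in 5 of 8, small peritoneal macrophage genes in 3 of 6 and NF-kB genes in 4 of 12 (7, 6 and 8 adjusted over the list alone; 1.18e-04, 1.04e-04 and 5.11e-04, against adjusted p = 0.46, 0.334 and 0.481 with an estimated correlation). In early libraries 1 and 2 the small macrophage list had a mean log2(CPM + 1) of 6.58 and 8.11, against 4.46 and 4.21 in 3 and 4 and 2.77 to 3.65 at baseline, and MHC class II 6.77 and 8.33, against 4.49 and 4.23 and 2.70 to 4.58. The GATA6 list had 9.31 and 8.51, against 10.17 and 10.09 in 3 and 4. The NF-kB list had 2.49 in early library 1 and 4.74 to 5.25 in the other 3, against 2.91 to 3.42 at baseline. Scavenger receptors fell in 2 of 11 (3 adjusted over the list alone; 0.00304, against adjusted p = 0.291 with an estimated correlation). The GATA6 list fell with no member called over all genes, and the LYVE1 and efferocytosis lists with 1 each (7.94e-04, 0.00349 and 0.0177, against adjusted p = 0.516, 0.46 and 0.38 with an estimated correlation). Mast cell markers rose as a list with no member called (0.00985, against adjusted p = 0.516 with an estimated correlation), to a mean log2(CPM + 1) of 5.82 in early library 2 and 3.09 to 3.37 in the other early libraries, against 3.09, 3.00, 2.36 and 0.081 at baseline.

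In all 171 of 9575 genes changed (131 higher, 40 lower). Without early libraries 1 and 2 the count was 88 (72 higher, 16 lower), with 42 of the 171 among them. It was 82 at equal depth (65 higher, 17 lower), 791 by DESeq2, 434 without the filter and 382 by limma-voom with quality weights. Leaving out baseline 1 gave 18, baseline 2 9, baseline 3 4, early 2 47, early 3 625 and early 4 516. Of the 32 named genes Marco alone kept its call in all 8 fits. Calls were lost for Arg1 without baseline 3 (adjusted p up to 0.0531), Jun without baseline 3 (adjusted p up to 0.0531), Lyve1 without baseline 1, 2 or 3 or early 2 (adjusted p up to 0.0869), Egr1 without baseline 1, 2 or 3 (adjusted p up to 0.0568), Ccl2 without baseline 2 or 3 (adjusted p up to 0.0568), Ccr2 without baseline 1, 2 or 3 (adjusted p up to 0.0712), Fcrls without baseline 2 or 3 (adjusted p up to 0.0568) and H2-Ab1 without baseline 1, 2, 3 or 4 or early 1 or 2 (adjusted p up to 0.142).

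From early to advanced stage in peritoneal macrophages, Jun fell from 619 ± 243 to 68.2 CPM (-3.20 ± 0.39, adjusted p = 0.0045), Ccr2 to 5.45 ± 1.69 CPM (-6.78 ± 1.12, adjusted p = 0.0151) and H2-Ab1 to 21.1 CPM (-4.93 ± 1.06, adjusted p = 0.0421). H2-Ab1 stood at 652.8 and 1737 CPM in early libraries 1 and 2 and at 44.98 and 40.1 CPM in early libraries 3 and 4. Cxcl13, a B cell chemokine made by peritoneal macrophages, rose from 453 to 2177 CPM (2.25 ± 0.31, adjusted p = 0.00862). Tjp1, the tight junction protein ZO-1 (chromosome 7, 65296165 to 65527850), rose from 30.0 to 115 ± 11.5 CPM (1.97 ± 0.31, adjusted p = 0.013), and Loxl2, a collagen cross-linking oxidase, from 2.09 to 23.5 ± 7.16 CPM (3.56 ± 0.62, adjusted p = 0.0202).

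Immediate-early and heat-shock genes fell in 11 of 17 (16 adjusted over the list alone; camera adjusted p = 1.47e-13, against adjusted p = 0.216 with an estimated correlation). NF-kB genes fell in 5 of 12, MHC class II genes in 4 of 8 and small peritoneal macrophage genes in 2 of 6 (9, 7 and 4 adjusted over the list alone; 1.80e-05, 6.90e-05 and 9.46e-04, against adjusted p = 0.499 with an estimated correlation for each). The MHC class II list, highest in early libraries 1 and 2, had means of 2.82 to 4.12 at the advanced stage, against 4.49 and 4.23 in early libraries 3 and 4. The cell cycle list fell with no member called over all genes and 6 adjusted over the list alone (1.05e-04, against adjusted p = 0.499 with an estimated correlation). Oxidative phosphorylation, B cell and mast cell lists fell (0.0116, 0.0276 and 0.00723). The GATA6 list rose with 1 member called, Cxcl13 (2 adjusted over the list alone; 8.41e-04). TREM2, scavenger receptor, lysosome and interferon lists rose (0.0385, 0.0471, 0.0401 and 0.0126). For these 8 lists the adjusted p = 0.499 with an estimated correlation, except 0.6 with an estimated correlation for the interferon list.

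In all 127 genes changed (50 higher, 77 lower). Without early libraries 1 and 2 the count was 88 (23 higher, 65 lower), with 40 of the 127 among them. DESeq2 called 607, edgeR without a filter 266, and limma-voom with quality weights 208 (101 higher, 107 lower). Leaving out early 1 gave 200, early 2 28, early 3 267, early 4 419, advanced 1 44, advanced 2 5, advanced 3 5 and advanced 4 15. Of the 27 named genes Cxcl13 and Jun kept their calls in all 8 fits. Calls were lost for Ccr2 without advanced 2, 3 or 4 (adjusted p up to 0.0884), H2-Ab1 without early 2 or advanced 1, 2, 3 or 4 (adjusted p up to 0.16), Tjp1 without advanced 2 or 3 (adjusted p up to 0.0532) and Loxl2 without early 2 or advanced 2, 3 or 4 (adjusted p up to 0.0884).

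Over the whole interval the planned fit called few genes in peritoneal macrophages, a count that rose steeply without early libraries 1 and 2. Tjp1 rose from 23.7 to 115 ± 11.5 CPM (SD, n = 4; 2.29 ± 0.29, adjusted p = 0.00387) and Loxl2 from 2.61 to 23.5 ± 7.16 CPM (3.16 ± 0.50, adjusted p = 0.0141), while Lyve1 fell from 148 ± 67.6 to 32.7 ± 11 CPM (-2.14 ± 0.33, adjusted p = 0.0141), Marco to 84.2 ± 35.6 CPM (-1.57 ± 0.29, adjusted p = 0.0258) and the proliferation marker Mki67 by -1.94 ± 0.39 (adjusted p = 0.0414). Ribosomal protein genes rose in 2 of 29 (22 adjusted over the list alone; camera adjusted p = 4.80e-15, against adjusted p = 0.844 with an estimated correlation). Cell cycle genes fell in 1 of 22 (5 adjusted over the list alone; 9.17e-09, against adjusted p = 0.844 with an estimated correlation). The interferon list rose with no member called over all genes and 1 adjusted over the list alone (1.31e-06, against adjusted p = 0.844 with an estimated correlation).

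In all 86 genes passed (49 higher, 37 lower). Without early libraries 1 and 2, 1072 passed (560 higher, 512 lower), including all 86. At equal depth 40 passed (25 higher, 15 lower), DESeq2 called 478 and limma-voom with quality weights 1525 (903 higher, 622 lower). Leaving out baseline 1 gave 7, baseline 2 8, baseline 3 25, advanced 1 52, advanced 3 3 and advanced 4 4. Of the 14 named genes Tjp1 alone kept its call in all 8 fits. Calls were lost for Loxl2 without baseline 1 or 2 or advanced 3 or 4 (adjusted p up to 0.0747), Lyve1 without advanced 3 or 4 (adjusted p up to 0.0679), Marco without baseline 1, 2 or 3 or advanced 1, 3 or 4 (adjusted p up to 0.116) and Mki67 without baseline 1, 3 or 4 or advanced 1, 2, 3 or 4 (adjusted p up to 0.136).

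**Figure D4:**
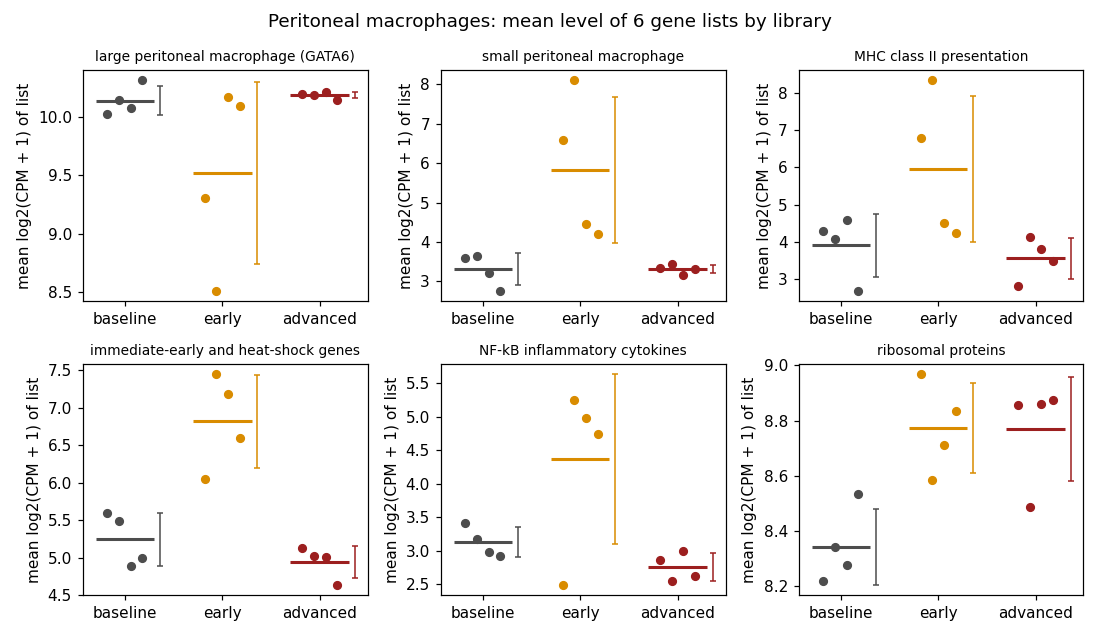
Mean log2(CPM + 1) of 6 gene lists in the peritoneal macrophage libraries by stage, with a separate vertical scale in each panel; dots are libraries, horizontal lines group means and side bars SD (n = 4). Early libraries 1 and 2 lie apart from the other early libraries in the small peritoneal macrophage and MHC class II lists.

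Whether the response to diet differed between populations was tested as the difference of the 2 changes. The planned fit of all 36 libraries with one spread gave 823 genes for early against baseline in the aorta against monocytes (582 higher, 241 lower), 947 against the peritoneum (591 and 356), and 77 (58 and 19) and 156 (140 and 16) for advanced against early. In simulated counts with the real spreads, 66 of 83, 77 of 95, 60 of 81 and 53 of 76 calls of that fit were false, with the limit given above. A fit with a separate spread in each population, chosen after seeing the data and with none of 1, 2, 6 and 3 simulated calls false, gave 7, 23, 5 and 17 genes, which are described first. It recovered none of the simulated 2-fold differences and 1.67, 3.51, 10 and 5.26% of the 4-fold ones, so these are not counts of all genes that differ.

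Clec4e showed the clearest difference: it rose early in aortic macrophages and stayed near 50.1 CPM at baseline and 45.9 early in monocytes and 153 and 156 in the peritoneum (adjusted p for the difference 5.2e-07 and 1.18e-06). Its size is not given, because the aortic baseline had no count. Compared with monocytes, the early change in the aorta was higher for the histone demethylase Kdm6b (0.98 against -0.84; difference 1.82 ± 0.34, adjusted p = 0.0389) and lower for Rmrp, the RNA of the ribonuclease MRP (0.07 against 2.53; -2.46 ± 0.44, adjusted p = 0.0124). Compared with the peritoneum it was lower for Lyz1 (-2.36 against 1.12; -3.47 ± 0.55, adjusted p = 0.00162), Fn1 (-2.17 against -0.28; -1.89 ± 0.38, adjusted p = 0.0114) and Ccr2 (-1.12 against 5.66; -6.78 ± 0.99, adjusted p = 0.00482), and higher for Lyve1 (0.50 against -1.62; 2.12 ± 0.40, adjusted p = 0.00765). From early to advanced stage, all 17 genes were higher in the aorta than in the peritoneum, among them Cxcl1 (1.46 against -3.79; 5.26 ± 0.98, adjusted p = 0.0193), Axl, a receptor for dying cells (1.28 against -2.47; 3.74 ± 0.66, adjusted p = 0.0193), and Egr1 (-0.17 against -4.28; 4.11 ± 0.72, adjusted p = 0.0231). Ccr2, Fcrls and H2-Ab1 differed in both intervals or in 1 of them and moved with peritoneal early libraries 1 and 2. Compared with monocytes, the change in that interval was lower in the aorta for Filip1l (-1.92 against 0.17; -2.09 ± 0.35, adjusted p = 0.00868).

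In the planned fit the lists that differed between aorta and monocytes from baseline to early stage, and held with an estimated correlation, were fibroblast markers (higher in the aorta; camera adjusted p = 3.07e-06 and adjusted p = 0.0469) and erythroid markers (9.71e-06 and 0.0159). T and NK cell, B cell, neutrophil, cell cycle, MHC class II and ribosomal lists were lower in the aorta (3.19e-05, 0.00215, 3.07e-06, 3.19e-05, 3.96e-04 and 4.52e-04, against adjusted p = 0.194, 0.194, 0.0976, 0.333, 0.333 and 0.333 with an estimated correlation). NF-kB and nonclassical lists were higher (0.00456 and 0.00456, against adjusted p = 0.576 and 0.333 with an estimated correlation). Between early and advanced stage T and NK cell markers were higher and erythroid markers lower in the aorta, and both held (5.27e-11 and 4.53e-05, against adjusted p = 0.019 and 0.019 with an estimated correlation). Against the peritoneum, MHC class II genes were lower in 9 of 10 from baseline to early stage (9 adjusted over the list alone; 9.55e-10, against adjusted p = 0.0893 with an estimated correlation). They were higher in 5 from early to advanced stage (9 adjusted over the list alone; 4.68e-09, against adjusted p = 0.0734 with an estimated correlation). Small peritoneal macrophage genes followed them (6.49e-09 and 8.59e-05, against adjusted p = 0.051 and 0.0927 with an estimated correlation). Both lists were highest in peritoneal early libraries 1 and 2. NF-kB, TREM2 and immediate-early genes were higher in 4 of 17, 3 of 16 and 8 of 19 in the later interval (14, 8 and 12 adjusted over the list alone; 1.32e-08, 7.08e-04 and 1.66e-07, against adjusted p = 0.0927, 0.0734 and 0.122 with an estimated correlation). With 1 weight per population limma-voom called 0 genes in all 4 differences (1244, 1370, 101 and 145 at an unadjusted p under 0.05).

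Early and advanced changes from baseline overlapped within populations, where both share the 4 baseline libraries. In monocytes 623 genes were called in the same direction at both stages (305 higher, 318 lower) and 10 in opposite ones. Independent lists give 50.2 higher and 46.8 lower. Simulated unchanged groups, which have no changes to share, gave 0. With 2 baseline libraries for each comparison the number was 182 or 185. The covariance of the fold changes was 0.217 against 0.028 with unchanged groups. In aortic macrophages 25 genes were shared (23 higher, 2 lower; 0 simulated; 0.166 and 0.00302 for independent lists), including Clec4e, Cxcl2, Fos and Lyz1, and 12 or 13 with the baseline divided. The aortic covariance was 2.35 against 0.787. In peritoneal macrophages 15 were shared (6 higher, 9 lower; 0.67 and 0.155 for independent lists), including Marco and Lyve1, and 0 with the baseline divided (edgeR). The covariance was 0.0527 against 0.0319, but the Pearson correlation, 0.264, lay below the 0.413 of unchanged groups, unlike in the other populations.

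Between populations, monocytes and peritoneal macrophages shared 54 genes in the same direction from baseline to early stage (46 higher, 8 lower; 6.3 and 1.74 for independent lists). Aortic and peritoneal macrophages shared 12, all higher (0.374 for independent lists; Fisher's exact test p = 3.85e-16). They included the NF-kB regulator Nfkbiz and the immediate-early genes Atf3, Fos, Egr1, Jun and Junb. The test takes genes as independent, which such a set need not be. Aortic macrophages and monocytes shared 5 (Fn1, H3f3b, Kmt2d, Egr1 and Jun, named because the count is small; 3 higher, 2 lower; Fisher's exact test p = 0.156 and 0.0358). At an adjusted p under 0.01 and at least 2-fold the 3 numbers were 2, 0 and 0. From early to advanced stage only monocytes and peritoneal macrophages shared genes, 2, and from baseline to advanced stage the pairs shared 10 (aorta and monocytes), 1 (aorta and peritoneum) and 24 (monocytes and peritoneum). All populations shared the pattern of deep baseline and shallow later stages.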

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

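The tests of small peritoneal macrophages, a lower monocyte share and a baseline batch, and the other splits, were chosen after the results were seen. Of 342 tests for a library far from the other 3 of its group, 27 passed the critical value, and chance gives about 1 in 20, or 17.1.

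Markers of other blood cells moved with stage in the monocyte libraries. A second set of mature neutrophil transcripts, fixed before it was measured, had a median log2 fold change of 1.83 at the advanced stage against baseline (8 of 9 higher, 5 called) and 1.13 early (6 of 9 higher, 2 called), which goes with neutrophils among the sorted cells. A lower share of monocytes would raise other cells' markers, as seen early for neutrophils (median 4.50), T and NK cells and B cells. The erythroid list fell (median -5.25, 3 of 3 lower), but it also depends on red cell lysis, so a lower share stays open. Neutrophils in the sort are a candidate explanation, although the gate and the red cell lysis are meant to remove other cells. S100a8 and S100a9, which neutrophils express strongly, reached 11260 and 15370 CPM in advanced library 3 and at most 3681 and 5090 in the others. A change of these transcripts within monocytes on the diet stays open and was not tested.

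Peritoneal early libraries 1 and 2 stood apart from every other peritoneal library. They may hold small peritoneal macrophages or recruited cells in place of large ones: the large macrophage list lay below baseline in both (median log2 ratio -0.95 and -1.63, upper quartiles -0.57 and -0.99), while the small macrophage list lay above (medians 3.37 and 4.88). A library of another sorted population under a peritoneal label is argued against, because both correlated best with the other peritoneal libraries (Spearman 0.891 and 0.878 over genes, against 0.696 and 0.766 with aortic and 0.713 and 0.770 with monocyte libraries). In early libraries 3 and 4, under the same diet, the large macrophage list had medians of 0.02 and -0.01 and the small macrophage list 0.71 (6 of 8 genes higher) and 0.87 (8 of 8). Whether the cells were recruited or gated differently stays open.

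Ribosomal protein transcripts rose from baseline in monocytes and peritoneal macrophages, where all baseline libraries were deeper. Thinned counts gave a median of 0.449 for early against baseline in monocytes, against 0.447 in full. Thinning hardly moves fold changes of genes with many reads, so a run or preparation that came with depth stays open. Transcript length alone is argued against. Genes matched on length and expression had medians of 0.023 (95% range -0.12 to 0.13) in monocytes and 0.0273 (-0.06 to 0.16) in the peritoneum. The list had 0.45 and 0.51. Over all genes, fold changes fell with length (Spearman -0.315 and -0.309). A batch shared by the baseline libraries cannot be told apart from chow, as the labels give no batch. The list also moved between early and advanced monocytes (median -0.24). A response to the diet stays open.

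Responses that differed numbered 823 genes early (aorta against monocytes), 947 (against the peritoneum), and 77 and 156 for advanced against early. For 3 of the 4 no other of 60 drawn splits gave as many. The highest other was 794 (median 361) for the 823, and 13 and 30 for the 77 and 156. Of simulated calls of this fit 60 of 81 and 53 of 76 were false, so the genes of the 77 and 156 stay open. The 823 and 77 came down to 643 and 14 without 1 library, against 794 and 13, so neither is read as beyond chance. For the 947, 3 of 60 splits gave as many (highest other 1053, median 442), and chance could not be excluded. For the population differences no other split gave as many (4044, 3769 and 3293, highest other 0, 0 and 140). Mixed groups carry those differences as spread, so this cannot exclude chance. The same held for the 9 stage comparisons, where no other of 35 splits gave as many (highest other in brackets). The aorta gave 37, 4 and 58 (1, 0 and 0) and monocytes 1023, 194 and 1798 (27, 0 and 0). The peritoneum gave 171, 127 and 86 (2, 8 and 7). The 4, 171, 127 and 86 also fell to 0, 4, 5 and 3 without 1 library.

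The remaining libraries lay far from the other 3 of their group, in mean log2(CPM + 1) of a list unless stated. In the aorta these were baseline 1 for erythroid markers (1.81, others 0), baseline 2 for mast cells (3.54, others up to 0.0207), early 3 for the GATA6 list (3.18, others 3.36 to 3.38), and early 1 for ribosomal proteins (8.19), immediate-early genes (10.04) and adipocyte markers (0.49). Aortic advanced 1 was lowest for detected genes (9216, others 12663 to 13293), NF-kB genes (7.51) and endothelium (0.46), and advanced 3 highest for matrix proteases (5.79) and adipocyte markers (0.74). In monocytes baseline 1 was highest for the GATA6 list (3.08), baseline 4 for NRF2 genes (6.00), early 1 for nonclassical (8.06) and unfolded protein response genes (5.71), and early 4 for mesothelium (0.22). Monocyte advanced 1 was lowest for immediate-early (5.0) and circadian genes (2.89), advanced 3 for efferocytosis genes (4.01) and advanced 2 for fibroblast markers (0.0), while advanced 2 was highest for T and NK cells (2.18). In the peritoneum baseline 4 was lowest for scavenger receptors (6.61) and B cells (1.5), early 1 for NRF2 genes (5.14), advanced 1 for scavenger receptors (6.29) and advanced 2 for ribosomal proteins (8.49), and early 2 was highest for mast cells (5.82).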

How the results depend on the processing

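Fits without the libraries that stood apart, without Rn45s, with one weight or with a separate spread per population were chosen after seeing the data. The others were planned. Size factors from DESeq2 (RLE) and leaving out Rn45s moved no count of genes by over 1.5 times. Among 849 pairs of a named gene and a comparison, 26870 of 29503 alternative values kept direction and side of the threshold, 2613 lost the call, 14 gained it and 6 reversed. The cause was not tested for any result that did not hold, except that thinning and leaving out libraries leave fewer reads or samples, and that the fit of all 36 libraries shares one spread, with a coefficient of variation of 65%. Depth limits comparisons with baseline, whose libraries were all deeper. In the aorta, where simulated 2-fold changes were not recovered, the spread was the wider limit (coefficient of variation 110%, against 19.1% in monocytes), and thinning did not lower the counts (52, 7 and 93 genes).

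Counts are in the order early against baseline, advanced against early, advanced against baseline. Without a filter on low counts edgeR called 151, 40 and 165 genes in the aorta, 373 for advanced against early in monocytes, and 434 and 266 for the first 2 in the peritoneum. It called 51 for the advanced against early response of aorta against monocytes. DESeq2 called 704, 47 and 548 in the aorta, 502 for advanced against early in monocytes, 791, 607 and 478 in the peritoneum, and 1495, 1716, 377 and 466 for the 4 responses (early against baseline in the aorta against monocytes, then against the peritoneum, then the same for advanced against early). limma-voom with quality weights called 235 and 151 for the last 2 in the aorta, 382, 208 and 1525 in the peritoneum, 7792 for peritoneum against monocytes, and 0, 0, 44 and 82 for the responses, with 726 and 753 genes at an unadjusted p under 0.05 for the first 2. Thinned to equal depth, the counts were 7 and 93 for the last 2 in the aorta, 574 and 1070 for the comparisons with baseline in monocytes, 82 and 40 for those in the peritoneum, and 538 and 585 for the early responses. The fit of all 36 libraries called 2113, 320 and 1816 in the aorta, 17, 0 and 33 in monocytes (299 at an unadjusted p under 0.05 for the count of 0), and 94, 83 and 2 in the peritoneum.

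Without the libraries that stood apart the counts were 114, 34 and 173 in the aorta, 91 and 1182 for the last 2 in monocytes, 88 and 1072 for the comparisons with baseline in the peritoneum, and 2008, 535 and 407 for the responses in the aorta against monocytes (both intervals) and against the peritoneum (advanced against early). With one weight per population limma-voom called 6892 genes for peritoneum against monocytes and 0 for each response (1244, 1370, 101 and 145 at an unadjusted p under 0.05), and a separate spread per population called 7, 23, 5 and 17.

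Leaving out each library in turn gave 12 to 120, 0 to 2 and 32 to 154 genes in the aorta, 548 to 1268, 34 to 321 and 1182 to 1732 in monocytes, and 4 to 625, 5 to 419 and 3 to 119 in the peritoneum. Population differences stayed at 3950 to 4835, 3629 to 4494 and 3138 to 4082. The responses ranged over 643 to 1749, 714 to 1899, 14 to 233 and 74 to 351. For the early responses the highest counts came without 1 aortic baseline library (1749, 1615, 1287 and 1316 against monocytes, 1899, 1779, 1455 and 1442 against the peritoneum). For advanced against early in the aorta against monocytes, 149, 179, 191 and 233 passed without aortic baseline 1 to 4, 124 and 47 without aortic early 3 and 4, 35 without aortic advanced 3, 14 and 36 without monocyte early 2 and 4, and 16, 22, 19 and 22 without monocyte advanced 1 to 4. Against the peritoneum 244, 276 and 351 passed without aortic baseline 2 to 4, 96 without aortic advanced 3, 74 without peritoneal early 2, and 88, 86, 75 and 87 without peritoneal advanced 1 to 4.

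Of 493 list tests 195 passed with camera's preset correlation and 42 with the correlation estimated from the data. fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 192, of which 139 were among the 195, and turned the direction of the lysosome list in aortic against peritoneal macrophages (down, adjusted p = 2.17e-04, against up and 0.922 with camera). Thinned counts gave 184 of 460, RLE size factors 198. Shared early and advanced genes, with the baseline divided both ways, were 12 and 13 in the aorta, 182 and 185 in monocytes and 0 and 0 in the peritoneum. At an adjusted p under 0.01 and 2-fold, genes shared between populations from baseline to early stage were 2 for monocytes with the peritoneum and 0 otherwise. They were 0 for each pair from early to advanced stage, and 2, 0 and 0 from baseline to advanced stage.

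Replicate numbers are shared between groups and the labels do not say that they pair samples. Deviations of same-numbered libraries from their group means correlated at -0.345 to 0.284 over 18 pairs of groups, and only in baseline monocytes and peritoneal macrophages were all 4 over 0.1 (0.103 to 0.284), where each library correlated best with its own number. The numbers were not taken to pair samples, but these 2 baselines, and the changes from them, may not be independent. A fit with the replicate number as a block left the aorta against monocytes at 3935 (1530 higher, 2405 lower) and called 114 genes for advanced against early in monocytes, 43, 39 and 14 in the peritoneum, and 255, 403, 10 and 44 for the responses, and 191 list tests.

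Reversed differences in response were Ticrr with limma-voom quality weights (0.51) and Egln3 without aortic early 2 (-0.44, within a leave-one-out range up to 5.58) against monocytes. Against the peritoneum they were Il1b with quality weights (0.94), without the libraries that stood apart (1.15) and without peritoneal early 2 (0.65, from a lowest of -4.10), and Klrb1c without aortic early 1 (-0.0389, up to 10.27 without another library).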

Other observations

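Further gene groups differed between the populations in the fit of all 36 libraries, which inflated aortic calls. Alternative activation genes were higher in 10 and lower in 3 of 14 members in the aorta than in monocytes (10 and 3 adjusted over the list alone; camera adjusted p = 1.18e-07, and adjusted p = 9.09e-05 with an estimated correlation), such as the mannose receptor Mrc1 (7.12 ± 0.35), and circadian clock genes in 8 of 14 (0.0157, and adjusted p = 0.0293 with an estimated correlation), such as the repressor Nr1d1 (3.84 ± 0.83). Platelet markers were lower in the peritoneum than in monocytes in 3 of 3 (5.13e-04, and adjusted p = 0.0254 with an estimated correlation), and endothelial markers in 3 of 3 (0.0162, and adjusted p = 0.0519 with an estimated correlation).

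Some aortic genes were near absent at baseline, with the limit given for Clec4e. Ogn, a matrix proteoglycan, had no count at baseline and was at least 563-fold higher early against a floor of 3 counts over the group (adjusted p = 0.0276). Dpt, a fibroblast matrix protein, had 1 count at baseline and an early to baseline ratio of 1720 (counting interval 306 to 68000; adjusted p = 0.0316). Fibroblast markers moved with both, as given above. At the advanced stage the lysosomal protease Ctsk was at least 546-fold higher than at baseline (adjusted p = 0.0406) and the growth factor Areg at least 449-fold (adjusted p = 0.0325), both with no count at baseline. These calls lay near the threshold: Ogn kept its call in 2 and the others in 1 of 8 fits that left out 1 library (adjusted p up to 0.0829 for Ogn, 0.14 for Dpt, 0.207 for Ctsk and 0.105 for Areg).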
